A study of Mus musculus with 17 samples.

How the data were processed

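RNA was extracted with Trizol from frozen upper somatosensory and parietal cortex of mice on a mixed Bl6 and 129S background, per the labels. Per the labels, total RNA had an integrity number of at least 9.8, and poly-A libraries were made with an Illumina TruSeq kit that does not mark strand and sequenced in reads of 100 bases. Per the submitters' processing notes, bases were called with bcl2fastq 1.8.4 and reads were mapped to mm9 with Tophat 2.0.4. The read counter, its annotation and its use of strand are not given in the sources used here, so overlapping and antisense genes and near-identical copies, such as C4b, Hspa1a and the Akr1c genes, are uncertain.

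The deposited counts are whole numbers of reads per gene symbol for 23284 genes in 17 libraries, with no normalization by the authors. The header of the count table stands one place off its columns. Columns were therefore taken by number, and their order was tested against the authors' normalized values, each of which is a constant times the counts of its library. Of the symbols, 25 had been turned into dates, and 93.1% matched a single gene of the GENCODE vM1 annotation of mm9, from which 1-based coordinates were taken. The ribosomal RNA gene Rn45s took between 2.43% and 10.7% of the counts of a library. At 15 weeks its share was 7.24 ± 2.45% (SD, n = 4) in Tsc1CKO and 5 ± 0.436% (SD, n = 3) in controls, and at 4 weeks 3.6 ± 0.767% and 4.26 ± 1.39% (SD, n = 5 each).

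The deposited comparison tables hold the authors' normalized signal per library, which is counts divided by a DESeq2 size factor. Their log2 values are the authors' fold changes with standard errors, and the score column is the authors' DESeq2 test statistic. The p-values in these tables are the authors' DESeq2 p and adjusted p, made with an FDR of 0.1 and listed under an adjusted p of 0.05, per the labels. What the fold changes contrast was tested by fitting DESeq2 to the counts, with a tolerance of 0.001 on the log2 scale.

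Libraries were grouped by age and genotype as the labels give them. Counts of every pair of replicates within a group were compared by chi-square, which gave 7.14 to 96.8 per degree of freedom over 29 pairs. No library was therefore counted as a repeat of another in its group. Pairs of libraries from different groups were not compared. The groups, tests, gene lists, rule for named genes and most alternative settings were fixed before the data were examined. Each comparison was fitted with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr by group, the robust quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. Genotype was tested within each age on the libraries of that age, the difference between ages on all 17, and age on the controls. CPM given as group means with SD are scaled over the genes tested, and CPM of single libraries, with the control mean, minimum or maximum beside them, over all genes counted. Standard errors are the size of the log2 fold change divided by the square root of the test's F. Tsc1 and Tsc2 were also tested by two-sided exact permutation of log2 CPM.

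The 46 fixed gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 where at least 3 members were tested. Camera with an estimated correlation, which held none of the calls, and fry, which tests whether the genes of a list move on balance one way, were alternatives. Members were also counted adjusted over the list alone. Named genes were Tsc1 and Tsc2, the 6 largest rises and 6 largest falls per genotype comparison and the 5 and 5 for the interaction and age, up to 4 members per described list by smallest p, a set of glial and neuronal genes fixed in advance, and the 3 largest and smallest fold changes of the authors' deposited tables. The rises and falls needed an adjusted p under 0.05, a mean log2 CPM of at least 1 and, except for the interaction, groups that do not overlap. Some genes that meet this rule are not reported here, and no others were put in their place.

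Alternatives were DESeq2 1.42.0, RLE factors, limma voom with quality weights, no filter, a filter at 1 CPM, an unrobust fit, an adjusted p of 0.1, a Y-linked covariate, a fit of all 17 libraries, the replicate number as a block and each library left out. Those added after seeing the data left out Rn45s or doubted libraries, used the pituitary gene Gh as a covariate, or removed trends with transcript length and GC content. On simulated data with known changes, edgeR recovered 65.7% of genes changed 1.5-fold and 86.6% of those changed 2-fold at 4 weeks, 4.48% and 56.7% at 15 weeks, 11.9% and 55.2% for the interaction, and 67.2% and 76.1% for age. These counts were drawn independently for each gene, with no library standing apart, so the rates need not hold for the real libraries. Of the edgeR calls, 12 of 178 at 4 weeks, 7 of 107 at 15 weeks and 5 of 106 for the interaction were unchanged genes. With DESeq2 these were 28 of 202, 38 of 151 and 25 of 139. Such shares depend on how many genes change, which here was 67, 67 and 66 at 1.5-, 2- and 4-fold.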

Results

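Messenger RNA was sequenced from the upper part of the somatosensory and parietal cortex of mice in which Tsc1 is deleted by a Cre recombinase under the mouse Gfap promoter (Tsc1CKO) and of control mice, at 4 and 15 weeks of age. Tsc1 encodes hamartin, which together with the product of Tsc2 restrains the growth-promoting kinase mTOR, and its loss causes tuberous sclerosis. The 17 libraries comprised 5 Tsc1CKO and 5 controls at 4 weeks, and 4 Tsc1CKO and 3 controls at 15 weeks. Total counts per library ranged from 13492007 to 24583430 at 4 weeks and from 16680450 to 20508464 at 15 weeks. Nothing in the labels states that each library came from a separate animal, so p-values measure the spread between these libraries.

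The first question was whether the targeted transcript itself changed. Tsc1 (mm9 chromosome 2, 28496748 to 28546687, plus strand, protein coding) was counted at 94.6 ± 8.3 CPM (SD, n = 5) in 4-week Tsc1CKO and 94.9 ± 6.19 CPM (SD, n = 5) in controls. The log2 fold change was -0.00 ± 0.07 (SE; two-sided exact permutation p = 0.944). At 15 weeks it was 101 ± 20.5 CPM (SD, n = 4) in Tsc1CKO and 117 ± 9.64 CPM (SD, n = 3) in controls. The log2 fold change was -0.20 ± 0.16 (SE; exact permutation p = 0.257, where 0.0286 is the smallest the design allows). Tsc1 counts per library lay between 1175 and 2455 over both ages, so depth does not limit this comparison. The interval of 2 SE on either side reached from -0.53 to 0.12 at 15 weeks. Tsc2 (chromosome 17, 24732882 to 24769574, minus strand) had a log2 fold change of 0.13 ± 0.07 (SE, adjusted p = 0.301) at 4 weeks and 0.10 ± 0.13 (SE, adjusted p = 0.654) at 15 weeks. Counts cover the whole gene, the labels do not say which exons are removed, and Cre acts in part of the cells, so the Tsc1 count does not check the genotype labels.

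**Figure D1:**
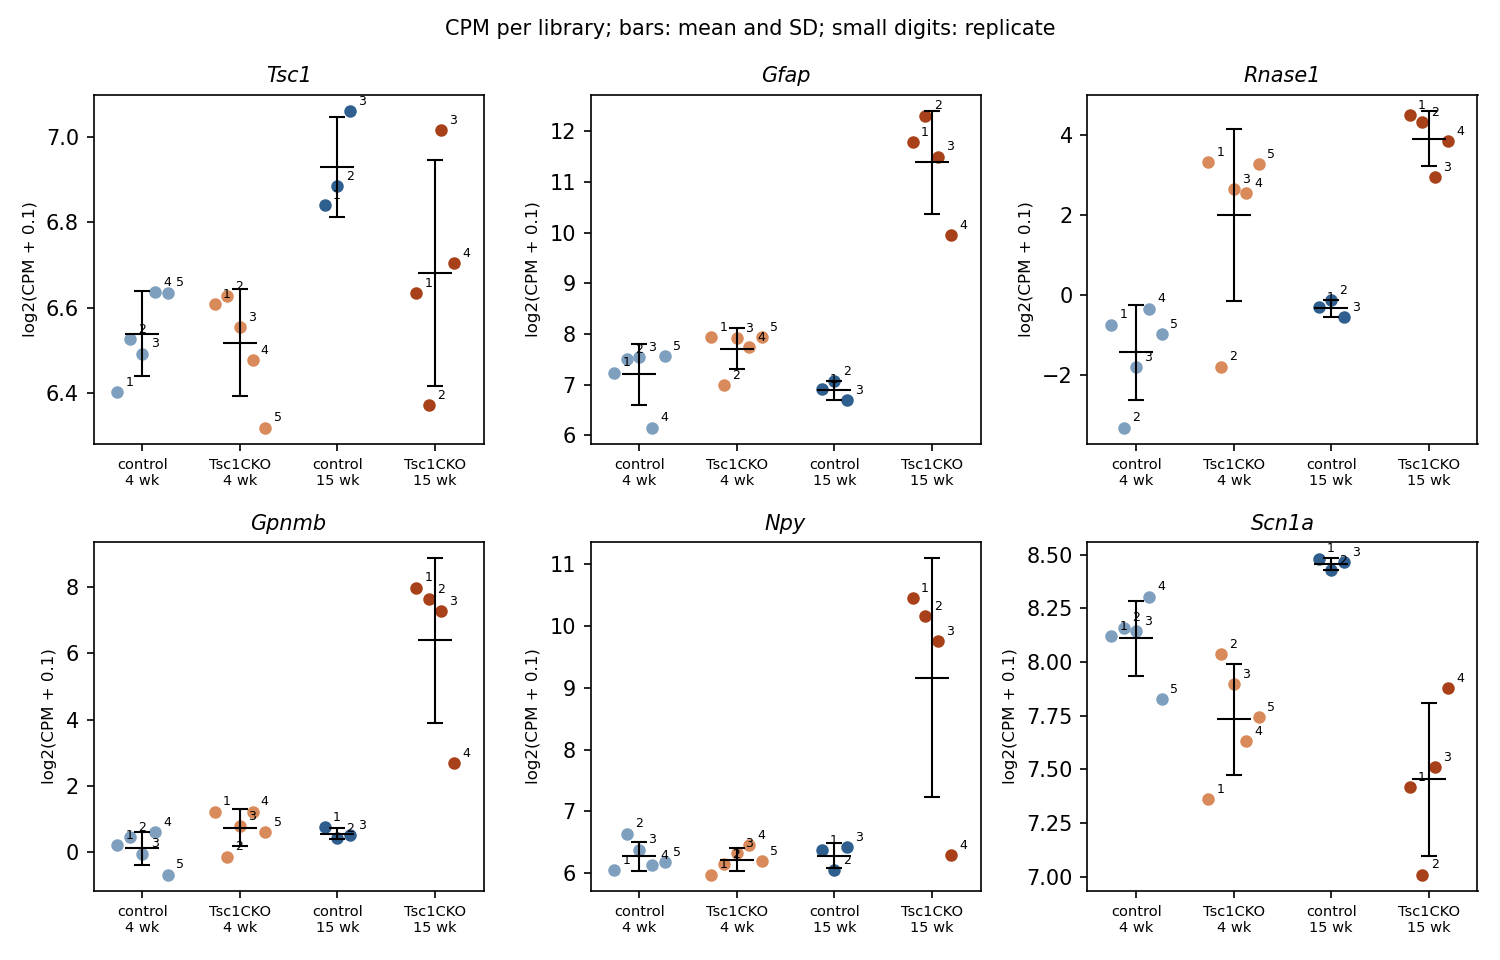
Expression of Tsc1, Gfap, Rnase1, Gpnmb, Npy and Scn1a in each library, as log2 of CPM plus 0.1 on the vertical axis, for control and Tsc1CKO at 4 and 15 weeks. Points are libraries with their replicate number, and bars give the mean and SD of the log2 values; Gfap averaged 3019 CPM in 15-week Tsc1CKO against 114 CPM in controls, while Npy, Gpnmb and Gfap were lowest in replicate 4 of that group.

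At 15 weeks, the question was how far the cortex of Tsc1CKO mice had departed from control. Gfap (chromosome 11, 102748650 to 102762226), the intermediate filament of astrocytes, rose from 114 ± 14.9 CPM (SD, n = 3) to 3019 ± 1599 CPM (SD, n = 4), a log2 fold change of 4.72 ± 0.52 (SE, adjusted p = 0.00445). The largest rises among genes whose groups did not overlap were in Gpnmb, a glycoprotein of phagocytic cells (6.79 ± 1.16), Ecel1, a peptidase of injured neurons (5.94 ± 1.20), Gfap, Rtp1 (4.63 ± 0.48), the ribonuclease Rnase1 (4.53 ± 0.42) and the galectin Lgals3 (4.45 ± 0.90). Among the deepest falls were those in the GTPase Rnd1 (-1.39 ± 0.31), the protocadherin Pcdh20 (-1.36 ± 0.29), the phosphatase Synj2 (-1.22 ± 0.20), the mTOR inhibitor Ddit4l (-1.21 ± 0.20) and the netrin receptor Unc5b (-1.17 ± 0.25). These are log2 fold changes ± SE over 4 Tsc1CKO and 3 control libraries. In all, edgeR's quasi-likelihood test called 504 genes higher and 63 lower of 15015 tested at a Benjamini-Hochberg adjusted p under 0.05. DESeq2 called 1391 higher and 739 lower, limma voom with quality weights 2773 and 2400, and edgeR without Tsc1CKO replicate 4 1997 and 1463, so the balance of directions depends on the settings and on that library. On data simulated for this age, 38 of 151 DESeq2 calls were unchanged genes, against 7 of 107 for edgeR. There only 67, 67 and 66 of 15015 genes were changed, by 1.5-, 2- and 4-fold, and no library stood apart. These shares therefore do not carry over to the real calls.

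Astrocyte genes rose in both the reactive and the general marker list. Of 13 measured genes of the pan-reactive astrocyte list, 6 rose over all genes tested and 9 when adjusted over the list alone, with a list median log2 fold change of 2.55 (camera adjusted p = 4.25e-13; adjusted p = 0.31 with an estimated correlation). Examples are Aspg (3.76 ± 0.50), the protease inhibitor Serpina3n (3.12 ± 0.39) and the oncostatin M receptor Osmr (2.55 ± 0.27). Of 29 general astrocyte markers, 11 rose and 0 fell, and 14 passed adjusted over the list alone (median 0.34; adjusted p = 0.267 with an estimated correlation). Among these, the connexin Gjb6 rose by 1.47 ± 0.12, the aldolase Aldoc by 1.18 ± 0.15, the potassium channel Kcnj10 by 1.05 ± 0.16 and Aldh1l1 by 0.97 ± 0.14. The filament gene Vim rose by 2.40 ± 0.34, the water channel Aqp4 by 1.10 ± 0.18 and the glutamate transporter Slc1a3 by 0.66 ± 0.12. The glutamate transporter Slc1a2 (0.23 ± 0.16, adjusted p = 0.392) and the connexin Gja1 (0.16 ± 0.16, adjusted p = 0.547) did not pass.

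Microglial and immune genes rose alongside. Of 28 activated microglia genes, 10 rose over all genes and 23 adjusted over the list alone, with a median of 1.20 (camera adjusted p = 3e-14; adjusted p = 0.373 with an estimated correlation). Among them were the tetraspanin Cd63 (2.24 ± 0.34), the lipid carrier Apoe (1.11 ± 0.14) and the receptor kinase Axl (0.81 ± 0.12). Of 21 complement genes, 6 rose and 14 passed adjusted over the list alone (median 0.97; adjusted p = 0.267 with an estimated correlation). They include C4b (3.72 ± 0.48) and C1qc (1.44 ± 0.27). Homeostatic microglia markers had a median of 0.67 with 1 of 19 called, Csf1r (0.77 ± 0.15), and 11 passing adjusted over the list alone (adjusted p = 0.472 with an estimated correlation). Aif1 (1.32 ± 0.48, adjusted p = 0.134), Cd68 (1.13 ± 0.33, adjusted p = 0.0808), C3 (2.08 ± 0.61, adjusted p = 0.0825) and C1qa (1.53 ± 0.36, adjusted p = 0.0514) did not pass.

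Some lysosomal genes and genes of the ATF4 response also rose. Of 42 lysosome and TFEB target genes, 10 rose and 18 passed adjusted over the list alone (median 0.41; camera adjusted p = 4.64e-09; adjusted p = 0.446 with an estimated correlation). Among them were the cholesterol carrier Npc2 (1.19 ± 0.21), the membrane protein Lamp2 (1.09 ± 0.15) and the glucuronidase Gusb (0.88 ± 0.15). Of 33 genes of the ATF4 and amino acid response, 6 rose and 17 passed adjusted over the list alone (median 0.43; adjusted p = 0.373 with an estimated correlation). They include Nupr1 (2.15 ± 0.33), Aldh1l2 (1.93 ± 0.28), Cth (1.25 ± 0.20) and Ddit4 (0.99 ± 0.18). Of 28 unfolded protein response and chaperone genes, 9 had positive values and 0 were called by edgeR over all genes or the list alone (median -0.14; camera adjusted p = 0.127). Cytosolic ribosomal protein genes had a median of 0.35 with 0 of 59 called (camera adjusted p = 0.00188; adjusted p = 0.651 with an estimated correlation), and Rplp0 was at 0.98 ± 0.29 (adjusted p = 0.0807). Nuclear-encoded oxidative phosphorylation genes had a median of 0.24 with 0 of 46 called (adjusted p = 0.69 with an estimated correlation), and Atp5g1 was at 0.74 ± 0.24 (adjusted p = 0.103). With the pituitary gene Gh as a covariate, chosen after seeing the data, the list nuclear-encoded oxidative phosphorylation genes, genotype effect at 15 weeks, had a median of -0.00099, near 0, and its call ended (adjusted p = 0.66), as did that of the ribosomal list. At this age Gh was at 52.7 CPM in Tsc1CKO replicate 2 and at most 2.69 CPM in the other libraries. An effect of pituitary RNA therefore cannot be told apart from the weight of that library.

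Neuronal genes moved in both directions. Seizure-responsive neuropeptides had a median of 1.36, with 3 of 15 called higher and 1 lower, and 12 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000318; adjusted p = 0.472 with an estimated correlation). Galanin (Gal) rose by 8.26 ± 1.68, proenkephalin (Penk) by 3.97 ± 0.79 and neuropeptide Y (Npy) by 3.49 ± 0.78, while Vip fell by 0.53 ± 0.11. In Tsc1CKO replicate 4 Gal was at 0.232 CPM with a small prior count included, against 21.5 CPM in the next lowest Tsc1CKO library. The size of its rise thus rests on the other Tsc1CKO libraries. In the list of voltage-gated sodium and potassium channels, 23 of 26 members had negative values (median -0.50; camera adjusted p = 1.23e-06; adjusted p = 0.472 with an estimated correlation). Scn1a was called lower (-0.94 ± 0.19) and Hcn4 higher (2.20 ± 0.50), and 12 were lower adjusted over the list alone. Of 22 glutamate receptors, 1 was called, Grin2d (-0.58 ± 0.12), and the median was -0.50 (adjusted p = 0.472 with an estimated correlation). Of 12 GABA-A receptor subunits, 6 were lower adjusted over the list alone, with a median of -0.35 (adjusted p = 0.373 with an estimated correlation). Upper cortical layer markers (median -0.49; adjusted p = 0.472 with an estimated correlation) and excitatory neuron markers (median -0.29; adjusted p = 0.373 with an estimated correlation) were shifted down with 0 members called in either list. The layer marker Rspo1 (-1.17 ± 0.29, adjusted p = 0.0605) and Neurod6 (-0.86 ± 0.20, adjusted p = 0.0533) came closest. The activity gene Fos had a log2 fold change of 0.13 ± 0.77 (adjusted p = 0.928).

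The 15-week count rests on single libraries. Replicate 4 of the Tsc1CKO group lay on the control side of the first principal component, at -22.5 against 32.7 to 64.9 in the other Tsc1CKO libraries and -43.2 to -36 in controls. Its Npy (78.3 CPM, against a control mean of 75.3) and Ecel1 (3.01 CPM against 2.08) were near control, whereas its Gfap (988 CPM against 115), Sparc (583 CPM against 129) and Ggta1 (24.1 CPM against 3.73) were not. These CPM are scaled over all genes counted, and the group means above over the genes tested. Sparc falls outside the rule for named genes and was chosen after its values were seen. Without Tsc1CKO replicate 4, 3460 genes were called, and without Tsc1CKO replicate 1 or 3 or control replicate 1, 2 or 3 the counts were 115, 292, 42, 39 and 48. Without Tsc1CKO replicate 2 it was 496. Gfap, Rtp1, Rnase1, Ggta1, Gjb6 and Osmr passed in all 20 alternatives run for this comparison. Ecel1, Lgals3, Npy, Penk and Hcn4 lost their call in 9 of the 20, Gpnmb, Rnd1, Pcdh20, Unc5b and Grin2d in 8, Vip in 7, Scn1a in 6, and Gal in 7 of 17. In all, 25 of 44 lists were called by camera with a preset correlation, 19 up and 6 down, and 0 of them with an estimated correlation.

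**Figure D2:**
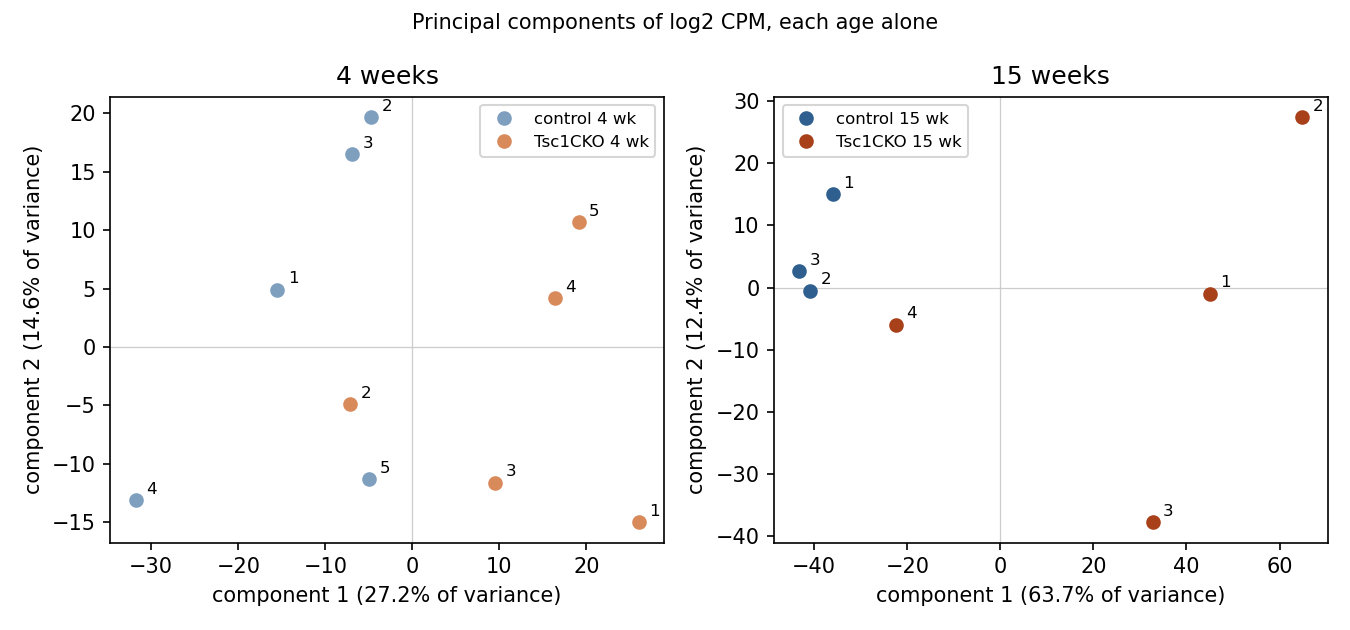
Principal components of log2 CPM at 4 weeks (left) and 15 weeks (right), with component 1 on the horizontal and component 2 on the vertical axis and the share of variance in percent on each. Points are libraries with their replicate number; component 1 held 27.2% of the variance at 4 weeks and 63.7% at 15 weeks, and 4-week Tsc1CKO replicate 2 (-7.13) and 15-week Tsc1CKO replicate 4 (-22.5) lay on the side of the controls.

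At 4 weeks, the question was what had changed in the younger cortex. The RNA-binding protein gene Zfp36l2 (chromosome 17, 84583271 to 84587287, minus strand) rose by 0.71 ± 0.09 (SE, adjusted p = 0.0105), the matrix protein gene Prelp by 1.21 ± 0.16 (adjusted p = 0.0254), the acetyl-CoA carboxylase gene Acacb by 1.21 ± 0.18 (adjusted p = 0.0314), Cmya5 by 0.94 ± 0.15 (adjusted p = 0.0413) and Bcar3 by 0.62 ± 0.10 (adjusted p = 0.0314). These are log2 fold changes over 5 and 5 libraries. The sixth gene called, 1700019G17Rik (0.96 ± 0.14), falls outside the rule for named genes and was added after its value was seen. Of 24 alternatives, Cmya5 lost its call in 13, Bcar3 in 12, Acacb in 11, Prelp in 8 and Zfp36l2 in 2. In all, edgeR called 6 genes higher and 0 lower of 14754 tested; at an unadjusted p under 0.05 there were 1448 higher and 1321 lower, against 738 by chance in all. DESeq2 called 381 higher and 220 lower, and limma voom with quality weights called 6 higher and 0 lower.

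Glial and vascular lists were shifted up at 4 weeks, with no member called over all genes. Of 29 astrocyte markers, 27 had positive values and 15 passed adjusted over the list alone (median 0.37; camera adjusted p = 1.91e-12; adjusted p = 0.405 with an estimated correlation). Of 21 endothelial markers 10 passed adjusted over the list alone (median 0.40), of 19 homeostatic microglia markers 8 (median 0.38) and of 14 oligodendrocyte precursor markers 7 (median 0.36), each with adjusted p = 0.405 with an estimated correlation. Examples are the astrocyte regulator Sox9 (0.85 ± 0.19, adjusted p = 0.0766), Gjb6 (0.87 ± 0.21, adjusted p = 0.0952), the endothelial kinase Tie1 (0.60 ± 0.12, adjusted p = 0.0583) and Vwf (0.72 ± 0.14, adjusted p = 0.0583). Others are the microglial receptors Mertk (0.51 ± 0.11, adjusted p = 0.0645) and Csf1r (0.50 ± 0.13, adjusted p = 0.0952), and the precursor genes Gpr17 (0.45 ± 0.12, adjusted p = 0.0966) and Sox10 (0.47 ± 0.14, adjusted p = 0.116). Gfap was at 0.48 ± 0.28 (adjusted p = 0.399), moving to 0.29 without control replicate 4 and to 0.61 without Tsc1CKO replicate 2. Vim was at 0.59 ± 0.18 (adjusted p = 0.13) and Aqp4 at 0.63 ± 0.21 (adjusted p = 0.16). Slc1a2 was at 0.30 ± 0.14, Slc1a3 at 0.37 ± 0.16, Gja1 at 0.37 ± 0.16 and Kcnj10 at 0.23 ± 0.14. None of these passed. Nor did Cd68 (0.37 ± 0.18), C1qa (0.20 ± 0.19), Aif1 (-0.04 ± 0.17), Npy (-0.05 ± 0.11) or Fos (0.18 ± 0.79), and C3 was too low to be tested.

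Lists shifted down at 4 weeks held metabolic and neuronal genes. Of 46 nuclear-encoded oxidative phosphorylation genes, 43 had negative values and 10 were lower adjusted over the list alone (median -0.15; camera adjusted p = 6.43e-10; adjusted p = 0.405 with an estimated correlation), among them Ndufa4 (-0.37 ± 0.10) and Ndufv2 (-0.33 ± 0.09). Of 12 GABA-A receptor subunits, 4 were lower adjusted over the list alone (median -0.25; adjusted p = 0.405 with an estimated correlation), with Gabra4 at -0.45 ± 0.12 and Gabra3 at -0.31 ± 0.08. Cytosolic ribosomal protein genes had a median of -0.13 with 0 of 60 passing either adjustment (adjusted p = 0.59 with an estimated correlation), and Rpl15 was at -0.38 ± 0.10. Excitatory neuron markers had a median of -0.10 (camera adjusted p = 0.0463; adjusted p = 0.405 with an estimated correlation). In all, 22 of 44 lists were called, 18 up and 4 down, and 0 with an estimated correlation.

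Single libraries weighed on the 4-week result as well. In control replicate 4, the mean log2 CPM of the astrocyte markers differed from the other controls by -0.53, that of the endothelial markers by -0.57, that of the homeostatic microglia markers by -0.56 and that of the precursor markers by -0.47. The difference was -0.41 for pericyte and smooth muscle markers and -0.99 for meningeal fibroblast markers, whose list was also shifted up in Tsc1CKO at 4 weeks (median 0.23; camera adjusted p = 0.0174; adjusted p = 0.617 with an estimated correlation). Tsc1CKO replicate 2 was at control level for Rnase1 (0.192 CPM, against 5.9 to 10.2 CPM in the other Tsc1CKO libraries and at most 0.696 CPM in controls) and Thbs4 (0.321 CPM, against 6.79 to 13.3 CPM and at most 1.41 CPM). For Agxt2l1 it lay between the groups (18.5 CPM, against 42.4 to 118 CPM and at most 12.2 CPM). It also lay above every control for Zfp36l2, Prelp, Acacb, Cmya5 and Bcar3, as the rule for named genes required. The pituitary hormone gene Gh, chosen after its values were seen, was at 134, 347, 1.22, 13.7 and 271 CPM in Tsc1CKO replicates 1 to 5 and at 34.2, 44.7, 94.3, 0.856 and 0.0404 CPM in control replicates 1 to 5. Without Tsc1CKO replicate 2, 594 genes were called, and without any one of the remaining libraries 0 to 3. With both Tsc1CKO replicate 2 and control replicate 4 left out, a choice made after seeing the data, 346 genes were called higher and 54 lower.

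**Figure D3:**
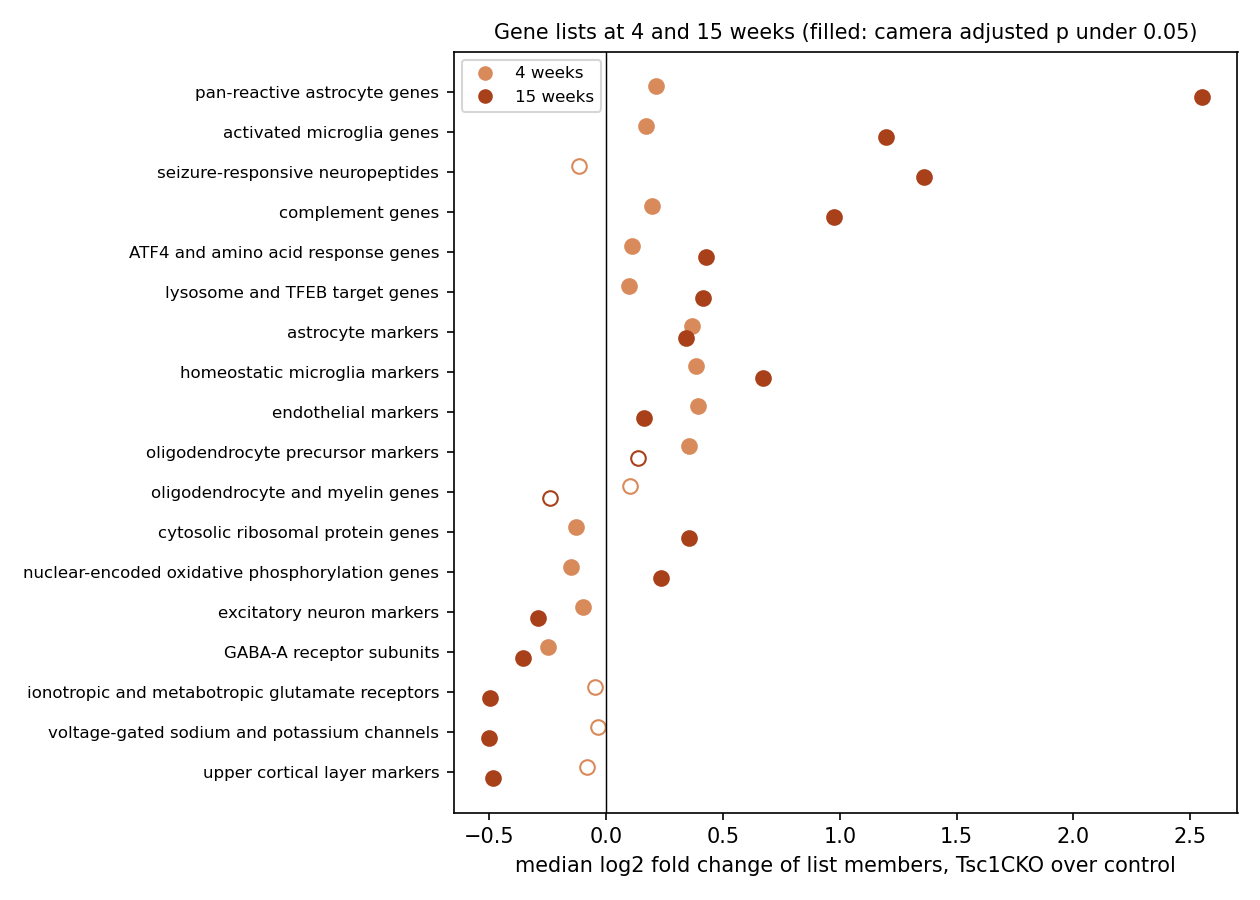
Median log2 fold change, Tsc1CKO over control, of the members of 18 gene lists at 4 weeks (light) and 15 weeks (dark). Each point is the median of a list, filled where camera with a preset correlation gave an adjusted p under 0.05; no list was called with an estimated correlation. The pan-reactive astrocyte list was at 0.21 and 2.55, and the oxidative phosphorylation list at -0.15 and 0.24.

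Whether the genotype effect itself differed between ages was tested as an interaction over the 17 libraries. The effect on Gfap was larger at 15 than at 4 weeks by 4.23 ± 0.55 log2 units (SE, adjusted p = 0.00396), on Penk by 4.23 ± 0.80, on the pan-reactive astrocyte gene Aspg by 3.32 ± 0.58, on A2m, a protease inhibitor, by 2.85 ± 0.53 and on the adhesion protein gene Tes by 2.82 ± 0.55. The effect was more negative at 15 weeks for Unc5b (-1.72 ± 0.28), Amotl2 (-1.04 ± 0.20), Wnt9a (-0.97 ± 0.19) and Mxd1 (-0.86 ± 0.15). Of 30 alternatives, Gfap passed in all, while Penk and Tes lost their call in 19, Wnt9a in 17, Amotl2 in 16, A2m in 15, Mxd1 in 14, Aspg in 13 and Unc5b in 5. In all, 27 genes had a more positive and 6 a more negative effect, of 15492 tested. Pan-reactive astrocyte genes differed with a median of 2.25 (camera adjusted p = 1.33e-10; adjusted p = 0.236 with an estimated correlation), activated microglia genes with 1.11 (adjusted p = 0.456 with an estimated correlation), seizure-responsive neuropeptides with 1.89 (adjusted p = 0.456 with an estimated correlation) and sodium and potassium channels with -0.46 (adjusted p = 0.59 with an estimated correlation). Oxidative phosphorylation genes differed by a median of 0.40 with 45 of 46 members above 0 (adjusted p = 0.59 with an estimated correlation), a call that held with Gh as a covariate. DESeq2 called 633 genes with a more positive and 436 with a more negative effect, and limma voom with quality weights 1820 and 2128. Without 15-week Tsc1CKO replicate 4 edgeR called 3503, 1739 and 1764 by direction, and without any other one library 4 to 26.

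Genes changed at 15 weeks were compared with the 4-week estimates, which come from separate libraries. Of 465 genes called higher at 15 weeks and tested at both ages, 435 (93.5%) had a positive log2 fold change at 4 weeks, with a median of 0.39, against 50.9% of all genes. Of 62 genes called lower, 59 were negative at 4 weeks, with a median of -0.21. None of the 6 genes called at 4 weeks (Zfp36l2, Prelp, Acacb, Cmya5, Bcar3 and 1700019G17Rik) was among those called at 15 weeks, where 0.191 would be shared by independent lists. At an adjusted p under 0.1, 146 genes were higher at both ages against 23.6 under independence, and with DESeq2 202 against 32.4. Across 14578 genes, which are not independent replicates, the fold changes at the ages had a Pearson r of 0.307 and a Spearman rho of 0.196. Without 15-week Tsc1CKO replicate 4, 1225 of 1792 higher genes were positive at 4 weeks, with a median of 0.13.

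The effect of age was taken in controls alone, 3 libraries at 15 against 5 at 4 weeks. The neuronal pentraxin receptor Nptxr rose by 1.89 ± 0.37 (SE, adjusted p = 0.00558), the activity gene Nr4a3 by 1.87 ± 0.61 and the heat-shock genes Hspa1b and Hspa1a by 2.55 ± 0.77 and 2.48 ± 0.60. Ppic fell by 1.67 ± 0.28, the locus Mir703 by 1.77 ± 0.25 and the aldo-keto reductases Akr1c14 and Akr1c18 by 2.09 ± 0.68 and 1.95 ± 0.66. Hspa1a with Hspa1b, and Akr1c14 with Akr1c18, are near-identical or related copies, and their split counts are uncertain. Of 18 alternatives, Akr1c14 and Akr1c18 lost their call in 10, and Nr4a3 in 9 and Hspa1b in 6 besides 1 each in which the sign turned. DESeq2 gave no adjusted p for Hspa1a and Hspa1b, and this was not counted as a lost call. In all, 3368 genes were higher and 2900 lower of 15007. Of 26 sodium and potassium channels 23 rose (median 0.54; adjusted p = 0.258 with an estimated correlation). Of 27 interneuron markers 16 rose and 2 fell (median 0.45; adjusted p = 0.0666 with an estimated correlation). Of 60 ribosomal protein genes 42 fell (median -0.54; adjusted p = 0.206 with an estimated correlation) and of 29 astrocyte markers 12 fell and 1 rose (median -0.33; adjusted p = 0.995 with an estimated correlation). The library codes of the ages do not interleave and no batch is given, so age and any batch between them cannot be told apart.

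The authors' deposited tables of differential expression were set against these fits. The authors' deposited table for 4 weeks lists 594 genes, 372 higher and 222 lower, led by Rnase1 (4.16), Thbs4 (3.47) and Agxt2l1 (2.80) and ending with Gm19522 (-0.78), Synj2 (-0.75) and 9330179D12Rik (-0.75). A DESeq2 fit of the 10 libraries without a filter gave log2 fold changes within 0.001 of all 594, and 6 of the 594 were among the edgeR calls. Here Rnase1 had a log2 fold change of 4.15 ± 0.87 (SE, adjusted p = 0.082) at 4 weeks, Thbs4 3.42 ± 0.74 (adjusted p = 0.0875) and Agxt2l1 2.80 ± 0.49 (adjusted p = 0.0645).

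The authors' deposited table named for 15 weeks lists 1062 genes, 616 higher and 446 lower, but its fold changes are not those of 15-week Tsc1CKO over 15-week control. A DESeq2 fit of all 17 libraries gave the difference of the genotype effect between 15 and 4 weeks within 0.001 of the listed value for 1061 of the 1062 genes, and the 15-week effect within 0.001 for 2, with a median absolute difference of 0.145. Its mean counts equal the mean over all 17 libraries for all 1062 genes. Gfap is listed at 4.23 in the authors' deposited table, whereas its fold change at 15 weeks alone was 4.72. The authors' deposited table puts Prl (19.66), Sprr1a (13.95) and Crct1 (12.33) highest and Gabra6 (-7.76), Cbln3 (-4.95) and Olfr464 (-3.00) lowest. Prl, a pituitary hormone, was counted at 0 CPM in each 15-week control library and at 1.12, 18.1, 0 and 0 CPM in Tsc1CKO replicates 1 to 4. At 4 weeks it ranged from 0.232 to 93.8 CPM in Tsc1CKO and from 0 to 16.8 CPM in controls.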

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

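The tests of single libraries and of cell makeup were chosen after the results were seen. The correction for transcript length and GC content was added after the data were seen but before its own result, and the splits of libraries were set beforehand. Of 127 groups of values tested for a library standing apart from the rest, 16 had one, where chance gives about 1 in 20, or 6.35.

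In 15-week Tsc1CKO, replicate 4 stood apart in 9 genes. The gap to the nearest library, as a share of the range, was 0.98 for Lgals3, 0.955 for Gal, 0.912 for Ecel1, 0.908 for Cdk1, 0.897 for Hcn4, 0.874 for Gpnmb, 0.87 for Penk and 0.844 for Npy, in each of which it was lowest, and 0.85 for Grin2d, in which it was highest. On a scale where controls average 0 and the other Tsc1CKO libraries 1, each library was placed on the 500 genes of smallest p chosen without it. The median position of replicate 4 was 0.233, above the highest control (0.0374) and below the lowest other Tsc1CKO library (0.799). That argues against a control under a wrong label, as does Gfap at 8.59 times the control mean. The spread of the share of the knockout level was examined for a mixture of knockout and control RNA. In replicate 4 that share had a median of 0.228. It spread over 1.06 between the 10th and 90th percentiles of genes (-0.12 to 0.936), and over 0.936 to 1.95 in the other Tsc1CKO libraries. Those libraries lie near the full knockout level, and their spreads were not scaled to the lower share of replicate 4. The spread therefore cannot tell a mixture from a milder phenotype. In genes picked afterwards the share in replicate 4 ran from 0.003 for Npy and 0.0262 for Gpnmb to 0.247 for Gfap and 0.874 for Aqp4. A mixture with a knockout like the others would give shares near one another, but genes picked afterwards do not decide the question. A milder phenotype in this library may also account for the pattern, and was not tested.

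In 4-week Tsc1CKO, replicate 2 was lowest with a gap of 0.773 for Bcar3 and 0.782 for Gfap. Placed in the same way, its median position was 0.174, within the controls (-0.449 to 0.32), which is what a control under a wrong label would show. It lay above every control for Agxt2l1 (18.5 CPM against at most 12.2 CPM), a gene picked afterwards. It also did so for Prelp (18.2 against at most 13.2 CPM), Zfp36l2 (27.5 against 20.7 CPM), Acacb, Bcar3 and Cmya5. Those genes were named only because the groups, this library included, do not overlap, so the rule set that outcome. For Rnase1, Thbs4 and Gfap it did not lie above every control. These genes do not decide the question. A swap with a 4-week control is argued against, since the highest control lay at 0.32 and the lowest other Tsc1CKO library at 0.577. A wrong label therefore may be a candidate explanation, and a knockout with little recombination stays open, as untested.

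Control replicate 4 at 4 weeks was lowest with a gap of 0.895 for Aqp4, 0.879 for Slc1a2, 0.776 for Gfap, 0.746 for Gja1 and 0.742 for Slc1a3. The astrocyte, microglia, endothelial and precursor lists were higher in Tsc1CKO at 4 weeks, and without this library their medians kept 69.8% of their size on average, so it is not the whole cause. Offsets for transcript length and GC content kept 89.3%, which argues against those trends as the whole cause. A lower share of neurons would raise oligodendrocyte genes as much as astrocyte markers; the log2 fold changes differed by 0.264 (exact permutation p = 0.19, n = 5 and 5), so this cannot be told apart from a change in the glia themselves. Mean log2 CPM was also compared between genotypes by exact permutation (n = 5 and 5). Astrocyte markers differed by 0.358 and homeostatic microglia markers by 0.32 (exact permutation p = 0.0317 for each). Endothelial markers differed by 0.372 (exact permutation p = 0.00794) and precursor markers by 0.317 (exact permutation p = 0.0397). Oligodendrocyte genes differed by 0.0941 (exact permutation p = 0.413). Excitatory neuron markers differed by -0.0951 (exact permutation p = 0.0317) and interneuron markers by -0.0814 (exact permutation p = 0.0714). These p-values are unadjusted, with control replicate 4 included.

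The genotype effect differed between 15 and 4 weeks in 33 genes by the interaction test. The differences were 4.23 for Gfap, 4.225 for Penk, 3.32 for Aspg, 2.85 for A2m, 2.82 for Tes, -1.72 for Unc5b, -1.04 for Amotl2, -0.97 for Wnt9a and -0.86 for Mxd1 in log2 units.

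Other splits of the same libraries were fitted to see whether chance can be excluded. At 4 weeks it cannot: 6 of 100 splits, the real one included, called at least the real 6 genes (highest other 245), and 6 of 100 at least the real 22 lists (highest other 25). The splits with 245, 103 and 16 genes exchanged only Tsc1CKO replicate 2 for a control, so they keep most of the real grouping. At 15 weeks chance cannot be excluded either: 2 of 35 splits called at least 567 genes and 4 of 35 at least 25 lists (highest other 29). The other split, with 3448 genes, grouped Tsc1CKO replicate 4 with the 3 controls, which points to the structure set by that library. For the interaction, 5 of 100 splits called at least 33 genes (highest other 2806) and 56 of 100 at least 16 lists (highest other 30), so chance is not excluded. The interaction splits with 2806, 2480 and 2387 genes grouped 15-week Tsc1CKO replicate 4 with the 3 controls. The split with 424 genes kept the real 15-week labels. The number of such splits therefore does not measure chance alone. For age in controls chance is excluded for genes, with 1 of 56 splits reaching 6268 (highest other 37), and not for lists, with 52 of 56 reaching 9 (highest other 24).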

How the results depend on the processing

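The alternatives that leave out doubted libraries, add Gh as a covariate or correct for transcript length and GC content were chosen after seeing the data. Where a cause is not given, the cause was not tested. Signs were compared only for values that passed in the reported fit.

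At 4 weeks 6 genes became 601 with DESeq2, 421 at an adjusted p under 0.1, 400 without the doubted libraries (Tsc1CKO replicate 2 and control replicate 4), 76 in a fit of all 17 libraries, 38 without a filter, 12 without the robust option and 0 with the Y-linked covariate. All 17 libraries looked male, with Ddx3y at 73.1 to 112 CPM and Xist at most 0.93 CPM. The Y-linked covariate therefore does not adjust for sex. The fits went on as follows. With 1 library left out the 4-week counts ranged from 0 (control replicate 2) to 594 (Tsc1CKO replicate 2). At 15 weeks 567 became 5173 with voom and quality weights, 3501 in the fit of 17, 2130 with DESeq2, 1833 at 0.1, 1290 with length and GC offsets and 105 with the Y-linked covariate, and 39 (without control replicate 2) to 3460 (without Tsc1CKO replicate 4) with 1 left out. Without Rn45s, 8 genes were called at 4 weeks, 546 at 15 weeks and 32 for the interaction. The interaction went from 33 to 3948 with voom and quality weights, 2863 without the doubted libraries, 1190 at 0.1, 1069 with DESeq2, 211 with Gh, 19 without a filter and 3 with the Y-linked covariate, and 4 to 3503 with 1 left out. The share of higher calls moved too: 88.9% at 15 weeks became 53.6% with voom and quality weights and 53.4% in the fit of 17, and 81.8% for the interaction became 46.1% with the same and 51% without the doubted libraries. The age count was 4897 to 6360 with 1 left out and 0 with the Y-linked covariate, which overlaps age because the Y-linked genes fell with it. There the signs turned for Hspa1b (-2.65), Hspa1a (-1.51), Nptxr (-0.18), Nr4a3 (-0.26) and the list of Y-linked and Xist sex genes (0.23), none past the threshold with this covariate.

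Lists called fell to 0 in every comparison with an estimated correlation, and fry called 0 at 4 weeks, 12 at 15 weeks (9 of them among the 25 of camera), 3 for the interaction and 12 for age (7 of them among the 9 of camera). With 1 library left out, camera called 15 to 25 lists at 4 weeks, 20 to 27 at 15 weeks, 15 to 20 for the interaction and 8 to 13 for age. The list nuclear-encoded oxidative phosphorylation genes, genotype effect at 15 weeks, turned to a median of -0.00099 with Gh as covariate (adjusted p = 0.66). With Gh, 8 of the 22 list calls ended at 4 weeks, 6 of the 25 at 15 weeks besides this one, and 0 of the 16 for the interaction. At 15 weeks Gh was high in Tsc1CKO replicate 2 alone, so the covariate cannot separate pituitary RNA from the weight of that library. Genes called higher at both ages went from 0 to 146 at 0.1, 202 with DESeq2, 191 without the doubted libraries and 1 without 15-week Tsc1CKO replicate 4. Genes shared with the authors' deposited tables by DESeq2 were 589 at 4 weeks, 1051 for the interaction and 757 for the 15-week effect. Tsc1 did not pass in any alternative, with -0.08 to 0.04 at 4 weeks and -0.33 to -0.02 at 15 weeks.

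With the replicate number as a replicate block, 12 genes were called at 4 weeks, 2842 at 15 weeks, where the block sets Tsc1CKO replicate 4 aside, and 2717 for the interaction. The numbers do not pair the libraries: libraries of the same number had correlations of -0.117 to 0.0556 at 4 weeks and -0.105 to 0.197 at 15 weeks. Over all alternatives, calls of named genes were lost in 46 values at 4 weeks, where few named genes were called, and in 348 at 15 weeks, and gained in 203 and 500.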

Other observations

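The test of the 15-week genes at 4 weeks and the values of pituitary genes were chosen after the results were seen. Further lists were shifted up at 15 weeks. Of 30 interferon response genes, 2 rose, Rsad2 (2.14 ± 0.42) and Ifit3 (2.12 ± 0.47), with 22 adjusted over the list alone and a median of 1.57 (camera adjusted p = 3.74e-08; adjusted p = 0.472 with an estimated correlation). Of 26 cell cycle genes, 2 rose, the kinase Cdk1 (4.06 ± 0.74) and the cyclin Ccnd1 (1.10 ± 0.21), with a median of 0.28 (adjusted p = 0.536 with an estimated correlation). The call of this list ended with Gh as a covariate, which at 15 weeks was high in Tsc1CKO replicate 2 alone. Of 21 perineuronal net and matrix genes, 4 rose, among them the hyaluronan receptor Cd44 (3.81 ± 0.76), the syndecan Sdc4 (1.16 ± 0.18) and the protease inhibitor Timp3 (0.85 ± 0.14), with a median of 0.49 (adjusted p = 0.267 with an estimated correlation). Of 17 cytokines and chemokines, 1 rose, Lif (3.06 ± 0.62), with a median of 1.01 (adjusted p = 0.472 with an estimated correlation). Values are log2 fold changes ± SE by edgeR. Of 20 alternatives, Cd44 lost its call in 9, Ifit3 in 8, Rsad2 and Ccnd1 in 6 and Lif in 5, and Cdk1 lost it in 5 of 17.

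Genes called higher at 15 weeks were examined as a set at 4 weeks, after members of the astrocyte, microglia and vascular lists were removed. Of 432 genes, 404 had positive values, with a median of 0.38 (camera p = 7.73e-46; p = 0.0351 with an estimated correlation of 0.39; fry p = 0.0111). The hypothesis is that part of the 15-week change may be present at 4 weeks in a smaller form. The doubts about single libraries at both ages remain open for it. The removal took the set from 465 to 432 genes, so glial and vascular genes outside the lists may remain. A shift in cell makeup at both ages therefore cannot be told apart from this hypothesis.

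RNA of pituitary hormones was present in some libraries. At 4 weeks, growth hormone (Gh) was at 134, 347, 1.22, 13.7 and 271 CPM in Tsc1CKO replicates 1 to 5 and at 34.2, 44.7, 94.3, 0.856 and 0.0404 CPM in control replicates 1 to 5. At 15 weeks, it was at 2.69, 52.7, 0.165 and 0.184 CPM in Tsc1CKO replicates 1 to 4 and at 0.937, 0.054 and 0 CPM in control replicates 1 to 3. Across the 17 libraries, Gh and the other pituitary genes had a Pearson r of 0.96 and a Spearman rho of 0.917 (one-sided permutation p = 1e-05 for each, the smallest that the resamples can give). The r was 0.949 without the 2 libraries farthest from the median of Gh, 0.943 within 4 weeks and 0.95 within 15 weeks. The rho was 0.882, 0.939 and 0.679 in the same order, and within 15 weeks Gh was high in Tsc1CKO replicate 2 alone.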
